A study of Mus musculus with 4 samples.

How the data were processed

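MicroRNA levels were measured by real-time PCR in round spermatids, the haploid germ cells that follow meiosis, from mouse testis. Per the labels' protocols, testes of adult mice aged 3 to 4 months were dispersed with collagenase and trypsin, round spermatids were enriched by centrifugal elutriation, and RNA was extracted with a kit that keeps small RNAs. The series' design text states that RNA of 20 mice was pooled for each genotype. There were 4 samples, 2 of wild-type and 2 of GRTH knockout mice. The labels do not say whether the 2 samples of a genotype came from separate pools, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, 500 ng of RNA was reverse transcribed with a pool of about 380 stem-loop primers and measured on a TaqMan low-density rodent microRNA array, a card of 384 wells with 1 PCR assay per well. The cycler and its threshold settings are not given in the sources used here. The labels name the strain in 2 ways, as C57BL/6 and as a mix with SV129J.

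The authors deposited raw cycle thresholds (Ct), the cycle at which a well's fluorescence crosses a set level, with wells that did not amplify marked as undetermined. A lower Ct means more target, and 1 cycle corresponds to at most a 2-fold change, so folds given here assume doubling in each cycle. The header of that table gives both knockout columns the same name. After subtraction of the reference described next, the first equalled knockout replicate 1 and the second knockout replicate 2 of the value table to 6 decimals, and they are called so here. The authors' value table holds ΔCt, a log2 scale that runs downward. Each of its values was found to equal the raw Ct minus the mean Ct of wells A11 and A12 of the same sample, so these 2 wells were the authors' reference. It is empty in 3 cells that hold a raw Ct. Per the file headers, the authors' table of ratios gives fold changes as ratios of knockout to wild type, 2 to the power of minus ΔΔCt, relative to a housekeeping gene and formed within a replicate number. Its ratios equalled those computed from the value table to 6 decimals. Its second column is empty in 30 wells for which both values exist, all of them wells without a ratio in replicate 1.

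The files name assays only by card well (row A to P, column 1 to 24), and no table that pairs wells with microRNA names was used here. The files therefore do not pair values with microRNAs, no microRNA is named, and the endogenous controls other than the 2 reference wells were not told apart from microRNA assays. Repeat wells of an assay, which were to be averaged first, could not be told apart either, so each well was tested singly. The 19 lists of microRNA families, clusters and cell type markers fixed before the data were examined were not tested, and neither was the set test planned for them. The rule for named wells, also fixed then, took up to 15 wells past the threshold per direction, filled to 10 with the largest differences without overlap, and added miR-469 and members of the lists. Since well numbers carry no identity, it was cut to the 2 wells with the highest and the 2 with the lowest log2 fold change. The reference wells and a few wells singled out after their values were seen are named besides. GRTH mRNA is not on the card, so the genotype labels could not be checked against it.

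Values were turned so that higher means more target, and each sample was centred on its mean over the 190 wells, other than A11 and A12, with a Ct of at most 35 in all 4 samples. Knockout was compared with wild type in these 190 wells with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with all 4 samples, no covariate and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. The fit had 2 residual and 1.54 prior degrees of freedom. Centring removes any change common to all wells, so the mean of the 190 wells was also compared with the reference wells per sample by an exact permutation test, which with 2 against 2 samples cannot go below a two-sided p of 0.333. Alternatives covered the reference (the authors' 2 wells, median centring, quantile normalization, none), the Ct limit, each sample left out, the replicate number as a block, and the variance model. U6 and the snoRNA controls could not be chosen as references by name, because their wells are not named in the files. Whether the wells used as references hold any of them cannot be told. On 20 simulated sets of 190 wells with the spread of these samples, the fit without the block recovered 6.07% of wells changed by 4 on the log2 scale and 0% of those changed by 2 or 1, with no false call. With the block it recovered 100% of changes of 4, 96.4% of 2 and 50.4% of 1, and 3.22% of its calls were false. The simulated sets gave all wells the same residual SD and both genotypes the same replicate deviation, as the blocked fit assumes. Wells of these samples differ in their spread, so these rates need not hold for the blocked calls below.

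Replicate numbers are shared between the genotypes, and the authors formed ratios within a number, but no label says that a number marks a shared day or batch. The difference between replicates 2 and 1 correlated between the genotypes across the 190 wells (Pearson r = 0.888), so the number behaved as a batch in the files, and blocked values and values within each replicate number are given beside the results. Precision is limited by 2 samples per group. The 4 wells A11, A12, B11 and B12 lay within 0.203 to 0.365 cycles of one another in each sample.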

Results

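The series addressed which microRNAs differ in round spermatids of mice that lack GRTH (also called DDX25), a testis-specific RNA helicase of the DEAD-box family. The card of 384 wells gave a Ct in 240 wells of wild-type replicate 1, 258 wells of wild-type replicate 2, 218 wells of knockout replicate 1 and 238 wells of knockout replicate 2. Without the 2 reference wells, a Ct of at most 35 was reached in 231 and 247 wells of the wild-type samples and in 212 and 222 wells of the knockout samples. The knockout samples thus had fewer detected wells than either wild-type sample, an order that chance gives, in one direction or the other, in 33.3% of cases with 2 exchangeable samples against 2. Over the 190 wells detected in all 4 samples, the mean Ct was 24.6 and 26.3 in wild-type replicates 1 and 2 and 26.4 and 28.0 in knockout replicates 1 and 2.

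The first comparison asked how the assays as a whole stood against the authors' reference wells, A11 and A12. The reference crossed the threshold at 17.7 ± 1.04 cycles in wild type and 24.4 ± 1.07 cycles in knockout (SD, n = 2 each), 6.66 cycles later in knockout. The 190 other wells crossed at a mean of 25.4 ± 1.22 cycles in wild type and 27.2 ± 1.13 cycles in knockout, 1.77 cycles later. Relative to the reference, the mean log2 level of the 190 wells was -7.73 ± 0.179 in wild type and -2.83 ± 0.0599 in knockout (SD, n = 2 each). The difference of 4.90 on the log2 scale, or 29.8-fold if each cycle doubles the product, was 4.81 within replicate 1 and 4.98 within replicate 2. It was larger than the spread between samples, and the exact two-sided permutation test gave p = 0.333, the smallest value that 2 against 2 samples allow.

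**Figure D1:**
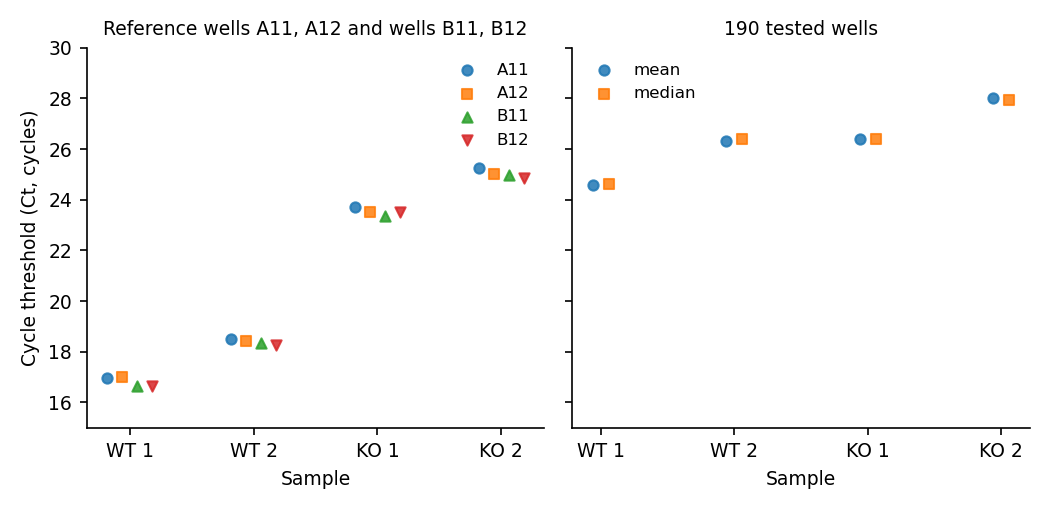
Cycle threshold (Ct, in cycles; lower means more target) of each wild-type (WT) and knockout (KO) sample for wells A11, A12, B11 and B12 on the left and for the mean and median of the 190 wells detected in all samples on the right. The wells on the left cross 6.57 to 6.76 cycles later in the knockout mean than in the wild-type mean, and the mean of the 190 wells 1.77 cycles later.

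In the authors' deposited table of fold changes, relative to this reference, 208 of 212 wells with a value stood above 1 in replicate 1 and 198 of 200 in replicate 2. The median ratio in the authors' deposited table was 33.4 in replicate 1 and 38.3 in replicate 2, and 187 and 182 wells exceeded 10. The highest ratio in the authors' deposited table was that of well C21 in both replicates, at 396 and 729. The lowest was that of well F11 in replicate 1, at 0.516, and that of well D11 in replicate 2, at 0.651. Tested on the authors' deposited log2 values with limma and Benjamini-Hochberg adjustment, 169 of the 190 wells rose and 0 fell in knockout. At an unadjusted p of 0.05, 172 wells passed. The raw Ct of the same wells, with no reference, gave 0 wells past the threshold in either direction and 34 at an unadjusted p of 0.05. On the raw scale 180 wells had a lower and 10 a higher mean level in knockout, with a median log2 difference of -1.52, while against the reference wells the median was 5.15.

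The second comparison asked which wells differed from the rest of the card, with each sample centred on its mean over the 190 wells. In knockout 6 wells fell relative to that mean and 0 rose (limma, Benjamini-Hochberg adjusted p of 0.05; 30 wells at an unadjusted p of 0.05). Whether these 6 wells hold 6 different assays cannot be told. Well F11 fell by 5.54 on the centred log2 scale, with a standard error of 0.542 and an adjusted p of 0.0448 from limma. Its raw Ct, before centring, was 18.6 ± 0.839 in wild type and 25.9 ± 0.435 in knockout (SD, n = 2 each), a raw log2 difference of -7.31. Well D11 fell by 5.50 on the centred log2 scale, with a standard error of 0.403 and an adjusted p of 0.0219 from limma. Its raw Ct was 22.9 ± 0.873 in wild type and 30.1 ± 0.927 in knockout (SD, n = 2 each), a raw log2 difference of -7.27. The fall of well F11 was 46.6-fold and that of well D11 45.2-fold relative to the mean of the card, if each cycle doubles the product. Of the other 4 wells that fell, well M15, named after its values were seen, fell by 4.00 on the log2 scale (limma adjusted p = 0.0487), but stood at 0.90 against the reference wells (limma adjusted p = 0.131). The rest were wells B11, B12 and J11, also named after their values were seen. They stood at -0.0081, -0.0647 and 0.287 against the reference wells, so they fell about as far as the reference did. Against the reference wells the log2 differences of wells F11 and D11 were -0.65 and -0.60 and did not pass (adjusted p from limma of 0.265 and 0.167). With the replicate block as well, the difference of well D11 passed at a limma adjusted p of 0.0225 and that of well F11 did not (0.0712). The 2 largest positive differences did not pass either: that of well C21 was 4.17 with a standard error of 1.26 and a limma adjusted p of 0.262, and that of well O1 was 2.95 with a standard error of 0.989 and a limma adjusted p of 0.300. Well C21 crossed at 31.6 ± 3.07 cycles in wild type and 29.2 ± 2.48 in knockout (SD, n = 2 each). Its mean came earlier in knockout even on the raw scale, but the groups overlapped there (limma adjusted p = 0.566). Well O1 crossed at 33.1 ± 0.189 cycles in wild type and 31.9 ± 0.0971 in knockout (SD, n = 2 each). Leaving out any single sample, wild-type replicate 1 or 2 or knockout replicate 1 or 2, left 0 wells past the threshold, with 12 or 13 at an unadjusted p of 0.05. The log2 difference of well O1 was 1.95 without wild-type replicate 1 and 3.94 without wild-type replicate 2, and that of well C21 was 5.48 and 2.86. With each sample left out, that of well F11 lay between -6.03 and -5.05 and that of well D11 between -5.74 and -5.26.

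With the replicate number as a block, 66 wells rose and 44 fell relative to the mean of the 190 (limma, adjusted p of 0.05). These 110 held all 6 wells that fell without the block. On the raw scale 10 of the 190 wells had a higher mean level in knockout, and against the reference wells 186 had. Most of the 66 thus had a lower raw level in knockout, and which wells rise depends on the reference. Wells C21 and O1 were among those that rose in this fit, with limma adjusted p of 0.00821 and 0.00931, and wells F11 and D11 among those that fell, both with a limma adjusted p of 0.00215. The log2 difference of well C21 was 3.82 within replicate 1 and 4.53 within replicate 2, and that of well O1 was 3.21 and 2.68. That of well F11 was -5.77 and -5.32, and that of well D11 was -5.40 and -5.60. Across the 190 wells the differences of both replicates had the same sign in 166 wells, or 87.4%, and correlated with a Pearson r of 0.877 and a Spearman rho of 0.822. These are correlations across wells, which are not independent replicates. The blocked fit rests on 1 residual and 2.22 prior degrees of freedom.

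**Figure D2:**
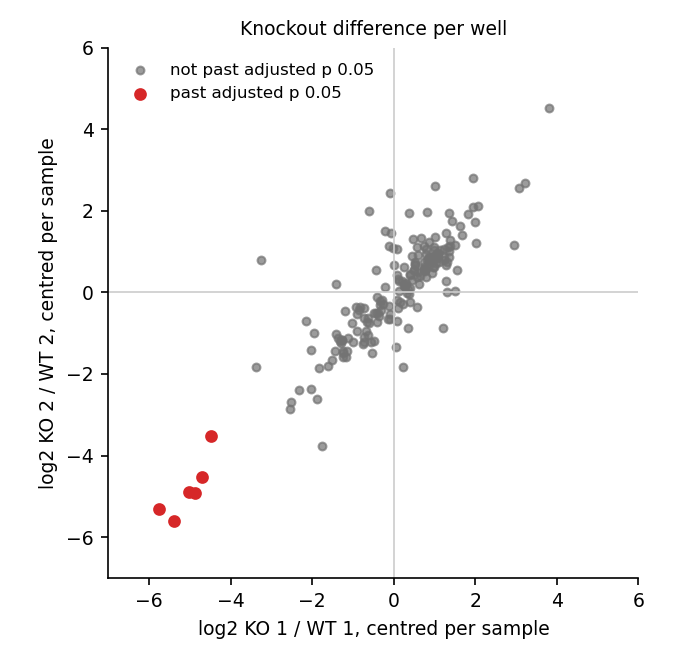
Knockout over wild type (KO and WT) on the log2 scale for each of the 190 wells, within replicate 1 on the x axis and within replicate 2 on the y axis, each sample centred on its mean over these wells. Each point is a well, and the 6 red points at the lower left are the wells past an adjusted p of 0.05 without the block.

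Samples of one replicate number also deviated together. The centred difference between replicates 2 and 1 of a well correlated between wild type and knockout across the 190 wells, with a Pearson r of 0.888 and a Spearman rho of 0.903. Its SD over wells was 1.50 in wild type and 1.57 in knockout, close to the SD of the knockout difference of 1.47 in each replicate.

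**Figure D3:**
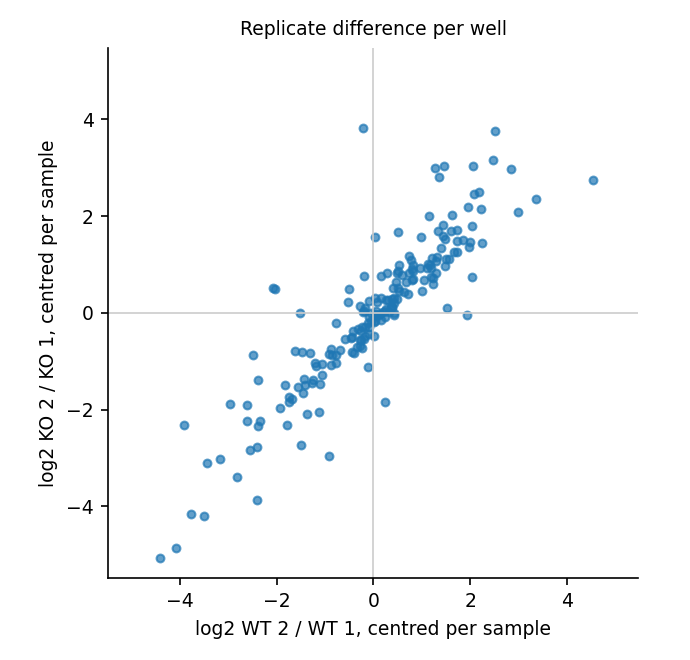
Replicate 2 over replicate 1 on the log2 scale for each of the 190 wells, in wild type (WT) on the x axis and in knockout (KO) on the y axis, each sample centred on its mean over these wells. Each point is a well, and the points follow the diagonal with a Pearson r of 0.888.

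By size alone, 51 of the 190 wells differed at least 2-fold between the group means without overlap of the samples, 24 of them higher and 27 lower in knockout. The groups did not overlap in 87 wells, or 45.8%, where chance gives 33.3% for 4 exchangeable samples and, in 100000 simulated wells with the shared replicate deviation of these samples and no genotype effect, 11.6%. The quartiles of the centred log2 differences were -0.68 and 0.88, with a median of 0.25. The same count was 182 higher and 0 lower against the reference wells, and 1 higher and 77 lower on the raw scale.

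Detection was counted on the raw scale, on which the mean of the 190 wells crossed 1.77 cycles later in knockout. A Ct of at most 35 was reached in both wild-type and neither knockout sample in 4 wells, and in both knockout and neither wild-type sample in 0 wells. Among the 4, well H11, singled out after its values were seen, crossed at 25.5 ± 0.896 cycles in wild type (SD, n = 2), was undetermined in knockout replicate 1 and crossed at 37.0 cycles in knockout replicate 2. With the knockout set at the limit of 35 cycles, it crossed at least 7.72 cycles later in knockout relative to the mean of the 190 wells. Well D24, another of the 4, crossed at 35.4 and 37.7 cycles in the knockout samples, and gave no bound beyond the later crossing of the whole card. These 4 wells were outside the 190, and none passed when knockout values past 35 were set to 35 and 222 wells were tested with limma. For well H11 that setting caps the difference, and its knockout values come from the limit rather than from a measurement. The result is therefore no evidence against a fall of this well.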

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

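The count of wells past the threshold, 6 without a block and all lower in knockout, depended on the reference and on the pairing. It stayed at 6 with median centring and quantile normalization, with the same 6 wells, and was 4 at a Ct limit of 32 and 4 with a variance trend, all among those 6, and 5 with an ordinary linear model, all lower and 2 of them among those 6. It was 169 (all higher) with the authors' reference wells, 0 on raw Ct, 3 with any Ct below 40 and 3 with later values set to 35 (222 wells tested), and 0 without each sample in turn, where the lone sample is assumed to vary like the other group. The 3 wells of both counts were among the 6. The replicate block gave 110 wells. The block's pairing comes from the data: the 2 pairs share only a number, although the replicate differences correlated between the genotypes (r = 0.888). Of the settings chosen after seeing the data, leaving out wells B11, B12, D11, F11 and J11 gave 0 of 185 wells (22 at an unadjusted p of 0.05), the reference wells with the block gave 184 (183 higher, 1 lower), and wells B11 and B12 as reference gave 174, all higher. Of the 190 wells, 79 lay below 0 when centred, 4 against the reference wells and 180 on raw Ct. The count of wells that differed at least 2-fold without overlap, 51, was 182 with the reference wells and 78 on raw Ct, ranged from 80 to 91 without each sample (where 1 sample against 2 overlaps less often), and lay between 39 and 61 otherwise. The shift of all wells against the reference, 4.90, ranged from 4.77 to 5.02 without each sample, was 4.90 with the replicate block (4.81 and 4.98 within replicates 1 and 2), and moved by less than the spread between samples under the other settings. The counts of detected wells kept their order between genotypes with any Ct below 40 (238 and 256 against 216 and 236) and with a limit of 32 (215 and 207 against 192 and 178). None of wells F11, D11, C21 and O1 changed direction, while wells M15 and J11, at -4.00 and -4.61, stood at 0.90 and 0.29 against the reference wells. Wells F11 and D11 lost their call in 10 and 7 of 15 alternatives. These include the fits without each sample, where a lost call may only reflect fewer samples. The log2 differences of wells F11 and D11 were -0.65 to -0.57 with reference wells, -7.31 and -7.27 on raw Ct and -6.03 to -5.05 without each sample. Well F11 also lost its call at nearly the same difference in 2 settings. These were any Ct below 40 (-5.53, limma adjusted p = 0.0601) and later values set to 35 (-5.54, limma adjusted p = 0.0527). Wells C21 and O1 gained a call in 4 of 15. They were not tested at a Ct limit of 32, because not all of their samples crossed by then. Late wells are limited by detection.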

Other observations

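Apart from the calls of the genotype comparison, the tests in this part were chosen after the values were seen. Of the 6 wells that fell relative to the card, 5 were in card columns 11 and 12, which held the reference wells and 19 of the 190 tested wells. The sixth, well M15, was in column 15, with a log2 difference of -4.00. The columns were noticed because of these wells, so a test of their share would not be valid and none is given. The 5 were wells B11, B12, D11, F11 and J11, singled out after their values were seen, with centred log2 differences of -4.90, -4.96, -5.50, -5.54 and -4.61, next to -4.99 and -4.80 for the reference wells A11 and A12. Well H11, which the knockout samples did not reach within 35 cycles, is in the same column. The 4 wells A11, A12, B11 and B12 differed by at most 0.365 cycles in any sample, while the other wells of the group differed from them in Ct. Using wells B11 and B12 as reference therefore had to give nearly the result of A11 and A12.

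The ratios above 1 in nearly all wells of the authors' table may come from the fall of the reference wells, by which all other wells are divided. The raw values fit this if the cards held equal amounts of cDNA: the median well did not rise but had a log2 difference of -1.52, while the reference wells crossed 6.66 cycles later. Position on the card, if shared by columns 11 and 12, would lower all their wells about as far as the reference wells (a centred log2 difference of -4.90). The tables argue against this as the cause of the fall: all 19 tested wells of these columns had a median of -0.037, 4.86 above that of the reference wells, with an SD over the wells of 2.60, and 9 of them lay above 0. An effect of position on single wells of these columns stays open. Less cDNA on the knockout cards stays open too: by itself it lowers all wells alike, but together with a rise of most other wells it would give the same values, and no value here gives the amount of cDNA. Also open are a class of assays placed at these positions that differs between the RNA preparations, and the knockout itself, which this design does not separate and which was not tested.

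By SD over all 190 wells, the replicate number moved single wells about as much as the genotype did. The centred difference between replicates 2 and 1 had an SD over wells of 1.50 in wild type and 1.57 in knockout, and that between knockout and wild type 1.47 in both replicates. The latter SD includes wells B11, B12, D11, F11 and J11, which fell furthest. Regardless of overlap, means differed at least 2-fold in 88 wells between replicate numbers and in 74 between genotypes. Splitting the samples by replicate number called 3 wells (42 at an unadjusted p of 0.05) where the split by genotype called 6, and the crossed split called 0 (0 at an unadjusted p of 0.05). The crossed split leaves both the genotype and the replicate difference in its residual, so its 0 calls are no negative control. Uneven filling of the card, which serves 2 rows per port, would tie the replicate difference to the 8 row pairs, but these held 2.59% of its variance (permutation test, p = 0.681). Noise of late cycles is argued against by the 37 wells with a Ct of at most 25 in all samples, where the difference still correlated between the genotypes (r = 0.975), although its size grew with Ct over all wells (Spearman rho = 0.321). A difference in reagents or cards stays open and was not tested. Pools of the 2 genotypes hold different mice, so a difference between pools would by itself not be shared between the genotypes. The correlation of 0.975 over these 37 wells argues against it as the cause of the shared part. It stays open if pools of a replicate number were prepared together, which the labels do not say.

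Row pairs differed in the centred knockout difference, with 8.50% of its variance between them over all 190 wells (permutation test, p = 0.0214, or 0.0322 after Benjamini-Hochberg adjustment over 3 row-pair tests) and 12.3% over the 185 wells without B11, B12, D11, F11 and J11 (p = 0.00155, adjusted 0.00465). Over these 185 wells the lowest medians were those of rows M and N, at -0.82 in replicate 1 and -0.76 in replicate 2. The highest was that of rows E and F in replicate 1, at 0.81, and that of rows G and H in replicate 2, at 0.83. Well M15, called lower in the comparison without the block, is in row M. The permutation test shuffled wells within these samples. Its p-values therefore do not tell whether other samples or cards would show the same, or whether the genotype is the cause.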
